A study of Mus musculus with 24 samples.

How the data were processed

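The analysed material was 24 RNA-seq libraries, 1 per female mouse aged 26 weeks, labelled as subcutaneous inguinal fat. The mice were WSB/EiJ, CAST/EiJ, NZO/HiLtJ or C57BL/6J animals, which makes 4 strains on 2 diets, with 3 mice in each of the 8 groups. The diets were a standard diet with 17% of energy from fat and a high-fat, high-sucrose diet with 45% of energy from fat, per the labels. Libraries were made from poly(A) RNA with a TruSeq kit, per the labels' protocols, and every library had the same lane label.

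The authors deposited a table of gene-level expected counts, which the submitters' processing notes attribute to RSEM 1.2.1 with Bowtie 0.12.8 and CASAVA 1.8.0, with the builds NCBIM37 and mm9 named. The notes do not give the role or order of these tools, and the deposited estimated counts are whole numbers without a statement of how they were rounded. A second deposited table holds an upper-quartile normalised signal, and each of its values equalled the sample's count divided by the 75th percentile of that sample's counts above 0, within 0.0005. All 24 samples were matched to a column of each table, and 0 columns were left over. The tables hold 37991 gene identifiers, of which 32919 (86.65%) matched a symbol in the reference name table, and the identifiers without a symbol held 1.515% to 2.352% of the counts of a library. Genes are given by symbol, and no coordinates are given. Totals ranged from 47651641 to 84009032 counts per library. Pairs of libraries within a group differed by a chi-square of 23.3 to 1578 per degree of freedom, far above counting error, so the libraries were treated as separate mice, as the labels state. Counting error covers only the sampling of reads, and the spread between mice sets the precision of group means.

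Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with the tool's filter on low counts by group, which left 20035 genes and removed 17956. Libraries were scaled by trimmed means (TMM), and gene levels are given in normalised CPM (counts over the scaled library total), group levels as mean ± SD. Exceptions are the marker genes of cell types, tissues and fat depots in single libraries, and the marker list sums. Those are in CPM over the unscaled library total, as are the thresholds set on them. A model with 1 coefficient per group was fitted to all 24 libraries, with 16 residual degrees of freedom, so that every comparison shared 1 estimate of the spread. The overall biological coefficient of variation was 40.06%. Each comparison used the quasi-likelihood F test of edgeR with Benjamini-Hochberg adjustment over the genes tested, and an adjusted p below 0.05 was the threshold for a call. Log2 fold changes are given ± their standard error. The comparisons were the high-fat minus standard difference in each strain and averaged over strains, the strain by diet interaction, the test of any difference between the 4 strains, and the 6 pairs of strains with both diets weighted equally. All p-values printed are 2-sided.

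The 24 gene lists were tested in 11 comparisons with camera from limma 3.58.1, with a preset correlation between genes of 0.01 and a prior count of 2, and adjusted over the lists within a comparison. In every list that passed, the median and mean log2 fold change had the sign of the test. The same lists were tested with camera's estimated correlation and with fry, and members were counted with adjustment over all genes and adjusted over the list alone. With an estimated correlation, the calls that held were the macrophage list for the diet in NZO/HiLtJ, the macrophage and cytokine lists in NZO/HiLtJ against C57BL/6J and against WSB/EiJ, and the cytokine list in NZO/HiLtJ against CAST/EiJ. Levels of 10 further marker lists of other tissues and of fat depots, written after the first counts were seen, were summed in each library. They covered reproductive tract, smooth muscle, brain, urothelium, liver, kidney, mesothelium, subcutaneous depot, intra-abdominal depot, and milk and basal epithelium.

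The groups, comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names Tst and the other members of its list, then for each comparison the 8 genes with the highest and the 8 with the lowest log2 fold change. Those genes had to pass the threshold, have no overlap between the libraries of both sides, reach a mean of 5 CPM on the higher side, and have a symbol that is not a predicted gene, clone or pseudogene. It also names up to 4 members per direction of each list with the smallest adjusted p, or where none passed the 2 members with the highest level. For space, the text names part of the list members so selected and leaves out genes of the 8 only from the lowest rank. Podnl1 falls outside the rule and was chosen after its values were seen. Genes of families with near-identical copies (stearoyl-CoA desaturases, cytochromes P450 of the 2 and 3 families, carboxylesterases, histocompatibility genes, immunoglobulins, Ifi202b, Cwc22, Hspa1a and Hspa1b) share reads, and how the authors' counting split these is uncertain. The library kit's strand setting is not stated in the labels, so overlapping and antisense genes are uncertain too. The role of the named builds is not stated, so whether reads of every strain were aligned to the same sequence is unknown. A loss of reads at sequence differences between strains was not tested, so differences in level between strains may in part reflect it.

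Alternatives were other scaling factors (relative log expression and upper quartile) and other count filters (none, or 1 CPM in 6 libraries). Other tools were DESeq2 1.42.0 and limma on the log2 of the deposited signal plus 1. Further alternatives were a minimum absolute log2 fold change of 1, fits of 1 strain or 1 diet alone, and leaving out each library in turn. The last added 3 covariates, the mean levels of the mammary epithelium, B and T lymphocyte and skeletal muscle lists. No list of smooth muscle, brain, urothelium, liver or adipocyte genes was a covariate. Chosen after seeing the data were limma with 0.01 added to the signal, leaving out replicate 1 of the CAST/EiJ high-fat group together with replicate 2 of the WSB/EiJ high-fat group, and leaving out the 6 libraries with Epcam at 5 CPM or more. These 6 were replicate 1 of the C57BL/6J high-fat group, replicate 1 of the CAST/EiJ high-fat group, replicate 3 of the WSB/EiJ standard-diet group and the 3 WSB/EiJ high-fat libraries. In that set WSB/EiJ has standard-diet libraries only, so the average diet effect and the interaction cover 3 strains and a pair with WSB/EiJ does not weight both diets equally. Without the 6 libraries 19748 genes were tested and the coefficient of variation was 20.77%.

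The steps were tested on simulated counts drawn from the means and library sizes of the real samples, with 200 changed genes. For the diet effect in C57BL/6J over 20035 genes, 32 of 100 genes changed 2-fold and 69 of 100 changed 4-fold were called, with 1 unchanged gene among the calls (0.98%). With the 6 libraries left out and 19748 genes, these counts were 58, 86 and 5 (3.36%). For NZO/HiLtJ against C57BL/6J over 20035 genes they were 49, 76 and 4 (3.1%). In a separate simulation of the diet effect in C57BL/6J with 200 genes changed 4-fold among 19835, edgeR recovered 142 with 2 unchanged genes called, DESeq2 158 with 40, and limma 161 with 31. The camera step was run on 20035 simulated genes with the oxidative phosphorylation list raised for the same comparison. It gave an adjusted p of 8.52e-40 for that list and called 0 of the other lists. The simulated genes varied independently, so that run does not cover lists whose members vary together. In every simulation counts were drawn gene by gene, so no library differed from its group through RNA of other tissue. The shares of unchanged genes among the calls therefore do not give the error rate of the real calls.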

Results

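Gene expression was measured by RNA-seq in fat labelled subcutaneous inguinal from 24 female mice. The mice belonged to C57BL/6J, a common reference strain, NZO/HiLtJ, a strain that becomes obese and diabetic, and CAST/EiJ and WSB/EiJ, both derived from wild mice. Each strain had 3 mice on the standard diet and 3 on the high-fat, high-sucrose diet. Totals per library ran from 47651641 counts in replicate 3 of the CAST/EiJ high-fat group to 84009032 counts in replicate 2 of the NZO/HiLtJ standard-diet group. The 10 most abundant genes held 5.92% to 13.0% of the counts of a library.

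The libraries differed in transcripts of cell types other than adipocytes. Adipoq, which encodes the adipocyte hormone adiponectin, lay at 4.75 CPM in replicate 1 of the CAST/EiJ high-fat group and at 621 CPM or more in every other library. Epcam, a marker of epithelial cells, reached 175 CPM in that library, 33.1, 58.5 and 11.9 CPM in the 3 WSB/EiJ high-fat libraries, 11.5 CPM in replicate 1 of the C57BL/6J high-fat group and 5.67 CPM in replicate 3 of the WSB/EiJ standard-diet group. It was at 2.8 CPM or less in the other 18 libraries. The summed level of 10 reproductive tract genes was 4300 CPM in replicate 1 of the CAST/EiJ high-fat group, against a median of 11.4 CPM over libraries. Smooth muscle genes summed to 9230 CPM in the same library and to 5020 CPM in replicate 3 of the WSB/EiJ high-fat group, against a median of 144 CPM. Brain genes summed to 3630 CPM in replicate 2 of the WSB/EiJ high-fat group, with 69.5 CPM as the next highest, and urothelial genes to 1130 CPM in replicate 3 of that group, with 27 CPM as the next highest. Alb, the albumin gene of the liver, lay between 76.8 and 873 CPM in the NZO/HiLtJ standard-diet libraries and between 4.44 and 20.5 CPM in the NZO/HiLtJ high-fat libraries. Comparisons are given for all 24 libraries, and also without replicate 1 of the CAST/EiJ high-fat group or without the 6 libraries with Epcam at 5 CPM or more. The set without the 6 holds no WSB/EiJ high-fat library, so its average over strains and its interaction cover the other 3 strains only.

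**Figure D1:**
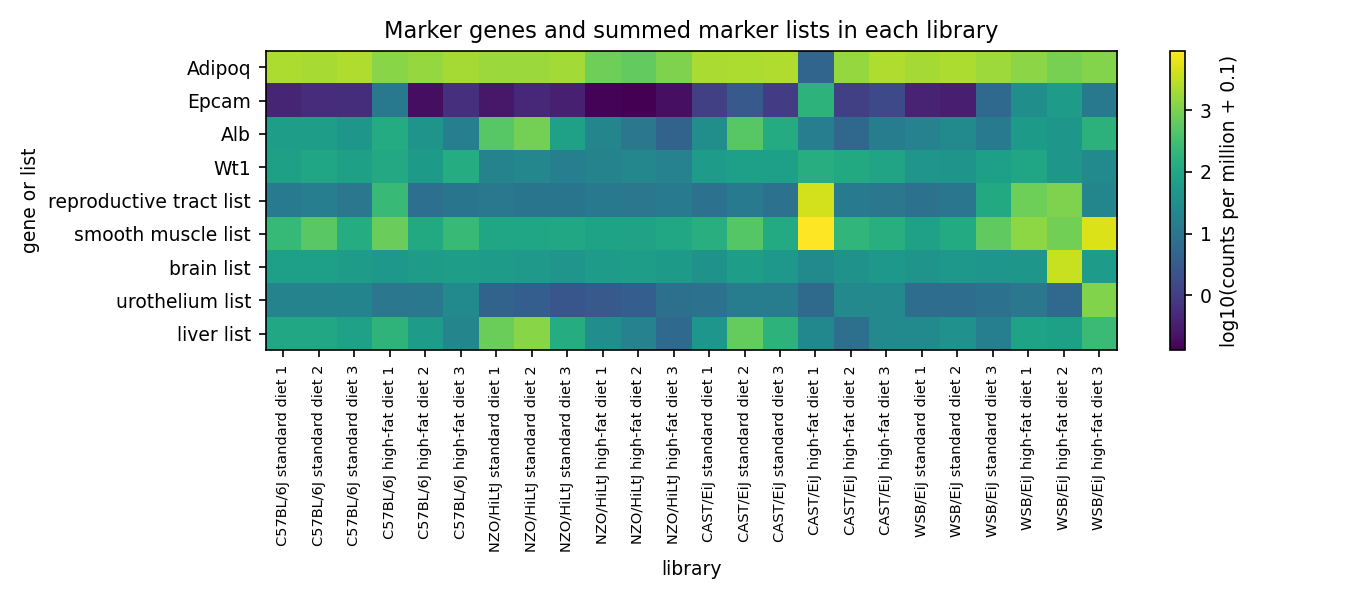
Level of 4 marker genes and the summed level of 5 marker lists (vertical axis) in each of the 24 libraries (horizontal axis), as the log10 of CPM plus 0.1 in colour. Replicate 1 of the CAST/EiJ high-fat group has Adipoq at 4.75 CPM and reproductive tract genes at 4300 CPM.

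The series set out to identify an adipocyte gene that protects against diabetes, and the gene of interest was Tst (ENSMUSG00000044986), which encodes thiosulfate sulfurtransferase, a mitochondrial enzyme of sulfide disposal. On the standard diet Tst lay at 99.3 ± 22.1 CPM in WSB/EiJ and 66.9 ± 37.3 CPM in CAST/EiJ, against 9.85 ± 4.29 CPM in C57BL/6J and 12.6 ± 0.71 CPM in NZO/HiLtJ (SD, n = 3). On the high-fat diet it lay at 23.4 ± 3.32 CPM in WSB/EiJ, 18.2 ± 14.6 CPM in CAST/EiJ, 11.5 ± 5.39 CPM in C57BL/6J and 6.91 ± 1.46 CPM in NZO/HiLtJ. Averaged over diets, Tst was higher than in C57BL/6J by 2.18 ± 0.36 (log2) in WSB/EiJ, with an adjusted p of 0.000178, and by 1.71 ± 0.35 in CAST/EiJ, with an adjusted p of 0.000793. With standard-diet groups only these differences were 3.33 and 2.76 and passed, and with high-fat groups only they were 1.03 and 0.66 and did not (adjusted p = 0.156 and 0.34). It was lower in NZO/HiLtJ than in WSB/EiJ (-2.37, adjusted p = 4.29e-05) and than in CAST/EiJ (-1.90, adjusted p = 0.000224). NZO/HiLtJ did not pass against C57BL/6J (-0.19, adjusted p = 0.752), where leaving out replicate 2 of the C57BL/6J standard-diet group or replicate 3 of its high-fat group turned the sign. The test of any strain difference gave an adjusted p of 1.38e-05. CAST/EiJ and WSB/EiJ did not pass against each other (-0.47, adjusted p = 0.31), but did without replicate 2 of the CAST/EiJ high-fat group (-0.90, adjusted p = 0.0297).

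With the high-fat diet, Tst fell in WSB/EiJ (-2.09 ± 0.50, adjusted p = 0.0111), where the 3 high-fat libraries lay below the 3 standard-diet ones. Leaving out any 1 library kept this change between -2.21 and -1.89, past the threshold. In CAST/EiJ it fell (-1.88 ± 0.50, adjusted p = 0.0441), with 109.9, 43.3 and 47.4 CPM on the standard and 6.03, 34.4 and 14.1 CPM on the high-fat diet. That call in CAST/EiJ was lost in 19 of the 24 fits that left out 1 library, and kept only without replicate 3 of the C57BL/6J high-fat group or replicate 2 or 3 of the CAST/EiJ or WSB/EiJ high-fat group. It was lost in the fit without replicate 1 of its high-fat group (-1.47, adjusted p = 0.158). No change passed in NZO/HiLtJ (-0.87 ± 0.49, adjusted p = 0.431) or C57BL/6J (0.22 ± 0.49, adjusted p = 1), and in C57BL/6J the sign turned without replicate 3 of either group. Averaged over strains Tst fell (-1.16 ± 0.25, adjusted p = 0.00551), and the average over the 3 strains other than WSB/EiJ, without the 6 libraries, was -0.67 with an adjusted p of 0.135. A difference of the diet effect between strains did not pass with all libraries (interaction adjusted p = 0.125), and passed without replicate 1 (adjusted p = 0.0411) or replicate 2 (adjusted p = 0.0307) of the CAST/EiJ high-fat group. With 3 covariates for mammary epithelial, lymphocyte and skeletal muscle transcripts, the diet effect on Tst did not pass. It was -0.89 ± 0.57 in WSB/EiJ (adjusted p = 0.385), -1.33 ± 0.58 in CAST/EiJ (adjusted p = 0.628) and -0.69 ± 0.27 on average (adjusted p = 0.213). Smooth muscle, brain and urothelial transcripts had no covariate.

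**Figure D2:**
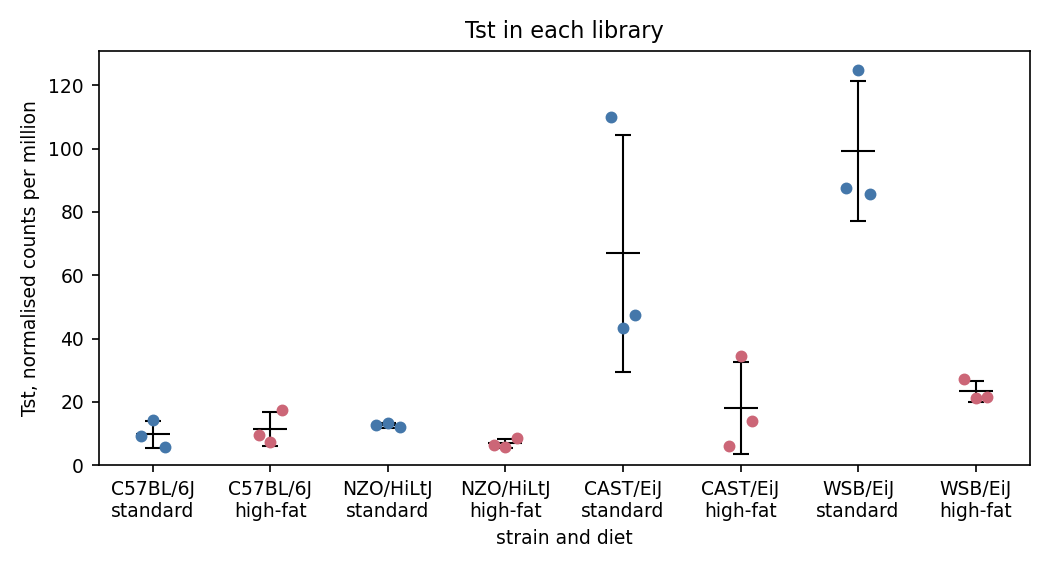
Tst in normalised CPM (vertical axis) in each library (points) of the 8 strain and diet groups (horizontal axis), with the mean and SD of 3 mice as horizontal and vertical lines. The WSB/EiJ mean is 99.3 CPM on the standard and 23.4 CPM on the high-fat diet.

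Of the 12 genes of the sulfide oxidation and sulfur amino acid list, 11 were measured. Averaged over strains, 5 fell with the high-fat diet, and 8 fell and 1 rose when adjusted over the list alone. Besides Tst these were Mpst, a sulfurtransferase closely related to Tst (-0.49 ± 0.09, adjusted p = 0.00252), Cth, the cystathionine lyase that makes cysteine (-0.76, adjusted p = 0.00814), Suox, the sulfite oxidase (-0.57, adjusted p = 0.00916), and Sqor, the sulfide:quinone oxidoreductase (-0.48, adjusted p = 0.0433). In the average of the 3 strains other than WSB/EiJ, without the 6 libraries, Mpst and Suox passed and Cth and Sqor did not. In WSB/EiJ, Cth (-1.62), Mpst (-0.80) and Tstd2 (-0.31) fell beside Tst, and without replicate 1 of the CAST/EiJ high-fat group Cdo1 (-1.56), Sqor (-0.66), Suox (-0.50) and Csad (-0.72) also fell in WSB/EiJ and Ethe1 rose (0.52). In NZO/HiLtJ only Cbs, the cystathionine synthase, fell with all libraries (-3.03, adjusted p = 0.0171), beside liver and kidney markers that were lower on the high-fat diet. Without the 6 libraries, which keeps all of NZO/HiLtJ, Mpst (-0.46), Sqor (-0.58), Suox (-0.87), Cth (-0.63) and Cdo1 (-1.09) fell there too. Adipocyte markers were lower in the same NZO/HiLtJ libraries. Adipoq went from 1730, 1680 and 1970 to 791, 621 and 1050 CPM, and Plin1 from 453, 492 and 520 to 371, 311 and 380 CPM. Whether the sulfide genes fell beyond the adipocyte transcripts in NZO/HiLtJ was not tested. In CAST/EiJ, Mpst (-0.78, adjusted p = 0.0376) and Cth (-1.44, adjusted p = 0.0414) fell. Neither passed without replicate 1 of the high-fat group (-0.598 and -1.045, adjusted p = 0.132 and 0.109). Both passed without the 6 libraries, which also leaves out that replicate (-0.59 and -1.038, adjusted p = 0.0158 and 0.0251). The list as a whole was lower on the high-fat diet by camera in NZO/HiLtJ (adjusted p = 0.00212), CAST/EiJ (0.0059), WSB/EiJ (0.00317) and on average (0.000256), and these 4 adjusted p were 0.324, 0.47, 0.665 and 0.322 with an estimated correlation. Between strains, Ethe1, the persulfide dioxygenase, was higher than in C57BL/6J in CAST/EiJ (1.42) and WSB/EiJ (0.82).

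The diet effect in C57BL/6J, the strain most used for diet-induced obesity, was called for 2 genes, both higher. Scd2, a fatty acid desaturase with near-identical relatives, rose from 146 ± 72.4 to 794 ± 215 CPM (SD, n = 3), a log2 change of 2.45 ± 0.36 with an adjusted p of 0.0242. Podnl1, a small matrix proteoglycan chosen after its values were seen, rose from 0.459 ± 0.09 to 2.46 ± 0.63 CPM (2.42 ± 0.34, adjusted p = 0.0242). By edgeR 734 of 20035 genes lay below an unadjusted p of 0.05, a smaller share than the 0.05 that chance gives. DESeq2 called 36 genes and limma 15. In the simulation of this diet effect, these 2 tools called 40 and 31 unchanged genes, against 2 by edgeR. Without replicate 1 of the CAST/EiJ high-fat group 19 genes rose and 2 fell, and without the 6 libraries 26 rose and 4 fell. Fits without 1 library called 0 to 21 genes. The count was 0 or 1 without any 1 of the C57BL/6J standard-diet libraries, without replicate 1 of the C57BL/6J high-fat group or without replicate 2 of the NZO/HiLtJ high-fat group. It was 4 to 21 without replicate 2 or 3 of the C57BL/6J high-fat group, replicate 1 of either CAST/EiJ group or replicate 3 of the WSB/EiJ high-fat group. Of the 24 gene lists 7 were higher by camera, among them cholesterol synthesis (adjusted p = 2.88e-12) and fatty acid and triglyceride synthesis (adjusted p = 2.3e-06), at adjusted p = 0.124 and 0.691 with an estimated correlation. Adjusted over the list alone, 3 of the 20 measured cholesterol genes and 1 of the 20 fatty acid genes rose. The groups did not overlap for 10.8% of all genes, against 10% by chance. They did not overlap for 2 of the 2 called genes, but these were selected on the same libraries, so that share is no added support.

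The diet effect in NZO/HiLtJ included higher macrophage genes, beside lower adipocyte markers. Adipoq lay at 1680 to 1970 CPM in the standard-diet and 621 to 1050 CPM in the high-fat libraries of NZO/HiLtJ. Itgax, which encodes the surface protein CD11c of dendritic cells and macrophages, rose from 28.7 ± 6.16 to 308 ± 62.6 CPM (3.42 ± 0.47, adjusted p = 0.000312, n = 3), and Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages, from 35.9 ± 11.9 to 674 ± 178 CPM (4.23 ± 0.78, adjusted p = 0.00372). The pan-macrophage markers Cd68 (1.89) and Adgre1 (2.02) and the scavenger receptor Msr1 (2.53) rose as well. Of the 15 macrophage genes 11 rose and 4 did not pass (12 rose and 1 fell adjusted over the list alone), and the list was higher both with the preset correlation (adjusted p = 5.04e-15) and an estimated one (adjusted p = 0.00687). The chemokines Ccl3 (2.99) and Ccl4 (2.51) and the stress genes Atf3 (2.63) and Fos (1.94) rose too. Zranb3, a DNA annealing helicase, rose from 8.95 ± 0.53 to 117 ± 27.4 CPM (3.71 ± 0.26, adjusted p = 2.89e-07). Others with large rises were Gpr50, a melatonin receptor relative (5.73), Fat3, a cadherin (4.79), Myh15, a myosin (4.11), Htr2b, a serotonin receptor (4.06), and Ptchd1, a membrane protein (3.54). The interaction test passed for Zranb3, Cd68, Adgre1, Msr1, Itgax and Atf3.

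Genes with the lowest log2 fold change in NZO/HiLtJ varied widely between the 3 standard-diet mice, whose libraries also held more liver and kidney markers. Liver markers summed to 753, 1290 and 130 CPM on the standard and 31.1, 17.9 and 5.84 CPM on the high-fat diet, and kidney markers to 9.74, 114 and 37.7 CPM against 1.68, 2.23 and 2.24 CPM. A1bg, a plasma glycoprotein gene, fell from 18.0 ± 15.4 to 0.0869 ± 0.0482 CPM, with -7.67 ± 1.56 and an adjusted p of 0.0073. Cyp2c40, Apoa5, Keg1, Cyp2c37, Ces1c, Cyp2a5 and Hamp2 had values of -7.53 to -6.10. In all, the diet effect in NZO/HiLtJ was called for 979 genes, of which 591 rose and 388 fell. The groups did not overlap for 46.5% of all genes, against 10% by chance. The share among called genes (976 of 979) is high by selection, since the calls come from the same libraries. Without replicate 1 of the CAST/EiJ high-fat group 1255 rose and 1120 fell, and without the 6 libraries 2127 rose and 1985 fell, and all 979 were called in both. The count fell to 303 and 640 without replicates 2 and 3 of the standard-diet group and to 502, 272 and 522 without replicates 1, 2 and 3 of the high-fat group. Besides the macrophage and sulfide lists, the cytokine, MHC class II, proliferation and stress lists were higher and oxidative phosphorylation lower, at adjusted p = 0.324, 0.694, 0.694, 0.324 and 0.799 with an estimated correlation.

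The diet effect in CAST/EiJ was called for 655 genes higher and 320 lower, 7 with the 3 covariates, and the number of calls depended on single libraries. Lcn2, a secreted lipocalin, lay at 920 ± 1590 against 2.17 ± 0.68 CPM (8.73 ± 2.21, adjusted p = 0.042, n = 3), and Ltf, the lactoferrin gene of secretory epithelia, at 390 ± 672 against 0.439 ± 0.23 CPM (9.79 ± 2.51, adjusted p = 0.0426). Plet1, Padi1, Slc16a14, Greb1 and Noxa1 were higher by 6.17 to 10.56. The lower genes included Myl2, a myosin light chain of muscle (-11.42), Cyp3a41a, Cyp3a41b and Cyp2a4, cytochromes P450 (-4.87, -4.99 and -4.51), Ighg2b and Ighg2c, immunoglobulin chains (-4.57 and -4.82), Slc38a3, a glutamine carrier (-4.52), and Pzp, a plasma protein gene (-4.48). None of these 15 genes passed without replicate 1 of the high-fat group, where the 7 higher ones had smaller changes of 0.64 to 4.15 and the 8 lower ones kept similar changes of -13.46 to -4.05. Without the 6 libraries, Greb1 (4.17, adjusted p = 0.0312) and Slc38a3 (-4.30, adjusted p = 0.038) passed. Skeletal muscle genes were lower, 9 of 17 by the test over all genes, with Ttn at 327 ± 559 CPM on the standard diet. Interferon response genes such as Ifit1 and Oas1a were higher in 7 of 15, and extracellular matrix genes such as Col1a1, Col1a2 and Timp1 in 8 of 21. Adjusted over the list alone these counts were 14 lower and 1 higher for muscle, 13 higher for interferon and 14 higher for matrix.

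For the diet effect in CAST/EiJ without replicate 1 of the high-fat group, 41 genes rose and 21 fell, and 42 of these were among the 975. Without the 6 libraries, 298 rose and 207 fell, with 267 among the 975. Leaving out replicates 1, 2 or 3 of the CAST/EiJ standard-diet group gave 122, 5 and 4 calls, and leaving out replicates 2 or 3 of the high-fat group gave 3707 and 4778. Any 1 of 14 libraries of other strains left out (the 3 C57BL/6J standard-diet libraries, replicate 2 of the C57BL/6J high-fat group, the 6 NZO/HiLtJ libraries, the 3 WSB/EiJ standard-diet libraries and replicate 1 of the WSB/EiJ high-fat group) gave 84 to 517 calls. The groups did not overlap for 20% of all genes, against 10% by chance. The share among called genes (759 of 975) is raised by selection, since the calls come from the same libraries. Of the 24 lists 15 passed by camera with all libraries, 7 without replicate 1 of the high-fat group and 8 without the 6 libraries, and none had an adjusted p below 0.442 with an estimated correlation. The matrix list was higher and the muscle list lower in both smaller sets (without replicate 1, adjusted p = 6.69e-06 and 0.00014). Both sets keep every CAST/EiJ standard-diet library, among which the muscle gene Ttn had an SD above its mean. Whether the lower muscle list rests on 1 of these libraries was not tested.

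The diet effect in WSB/EiJ, a strain resistant to diet-induced obesity, included lower lipid synthesis genes. Adipoq went from 2000, 2350 and 1760 CPM on the standard to 1340, 937 and 1140 CPM on the high-fat diet. Plin1 went from 534, 492 and 411 to 355, 230 and 337 CPM. Smooth muscle genes summed to 76.5, 118 and 589 against 1400, 869 and 5020 CPM, and Epcam was at 11.9 CPM or more in all 3 high-fat libraries. These CPM are unscaled. The scaling factors were 0.8234 to 0.9355 on the standard and 1.0283 to 1.1349 on the high-fat diet. Scaling therefore makes the falls of Adipoq and Plin1 larger. Acly, the ATP citrate lyase that supplies acetyl-CoA, fell from 21080 ± 6840 to 3603 ± 2500 CPM (-2.55 ± 0.84, adjusted p = 0.0395, n = 3), and Elovl6, a fatty acid elongase, fell by 2.34. Me1, the malic enzyme (-2.54), and Dgat2, a triglyceride synthase (-2.13), fell as well. Of the 20 fatty acid and triglyceride synthesis genes 8 fell and 12 did not pass (13 fell adjusted over the list alone), and 8 of 22 oxidative phosphorylation genes fell (17 over the list alone). Among adipocyte genes, Slc2a4, the insulin-regulated glucose carrier, fell (-1.52), and of insulin signalling genes Hk2, Insr and Tbc1d4 fell. Matrix genes rose in 10 of 21, with Col1a1 at 793 ± 225 against 197 ± 41.8 CPM. Proliferation genes rose in 9 of 11 (11 over the list alone), with Mki67 at 20.9 ± 17.4 against 2.12 ± 0.67 CPM. The epithelial keratins Krt7 (4.02), Krt8 (4.50) and Krt18 (4.41) rose, and Prlr, the prolactin receptor, fell (-0.99). Mill1, a class I-like gene, fell from 22.6 ± 4.23 to 0.429 ± 0.43 CPM (-5.71), and Ccn5, Adcy10, Cldn22, Pik3c2g, Aspg and Ttc25 fell by 2.61 to 4.65.

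Genes with the highest log2 fold change for the diet effect in WSB/EiJ were near 0 on the standard diet and varied widely on the high-fat diet. Sptssb, a subunit of serine palmitoyltransferase, lay at 75.7 ± 131 against 0.00582 ± 0.01 CPM, and Krt15, a basal keratin, at 44.9 ± 77.6 against 0.00574 ± 0.01 CPM. Frmpd4, Spock1, Gpa33, Dlgap2 and Mgat5b had a count of 0 in all 3 standard-diet libraries and means of 18.9 ± 31.9, 12.8 ± 21.9, 12.1 ± 19.1, 10.6 ± 17.7 and 7.44 ± 12.6 CPM on the high-fat diet. Gjb6 lay at 12.7 ± 15.1 against 0.00458 ± 0.008 CPM. Replicate 3 of the high-fat group, the library with urothelial genes at 1130 CPM, had the highest levels of Sptssb (227 CPM), Krt15 (135 CPM), Gpa33 (34.2 CPM) and Gjb6 (29.6 CPM). Replicate 2 of that group, with brain genes at 3630 CPM, had the highest levels of Frmpd4 (55.7 CPM), Spock1 (38 CPM), Dlgap2 (31 CPM) and Mgat5b (22 CPM), and the other 2 high-fat libraries were below 1 CPM for these 4. In all, 2579 genes were higher and 1726 lower, and without replicate 1 of the CAST/EiJ high-fat group 4446 and 3658. With the 3 covariates 36 were higher and 44 lower, and limma gave 1177 higher and 1561 lower. Leaving out replicates 1 or 2 of the WSB/EiJ standard-diet group gave 639 and 1450 calls, and leaving out replicate 2 of its high-fat group gave 1543. The 3 high-fat libraries are among the 6 with Epcam at 5 CPM or more, so the comparison without these could not be made. Groups did not overlap for 39.97% of all genes, against 10% by chance. The share among called genes (3441 of 4305) is raised by selection, since the calls come from the same libraries. Of the 24 lists 11 passed by camera, and none had an adjusted p below 0.665 with an estimated correlation. The lists higher by camera were proliferation, matrix and mammary epithelium. The mammary epithelium list includes general epithelial genes such as Krt7, Krt8, Krt18 and Epcam. Its milk protein genes Csn2, Csn3, Wap and Lalba stayed at 0.154 CPM or less in every library. The 8 lower lists included fatty acid synthesis (adjusted p = 1.91e-05) and oxidative phosphorylation (adjusted p = 1.18e-07).

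**Figure D3:**
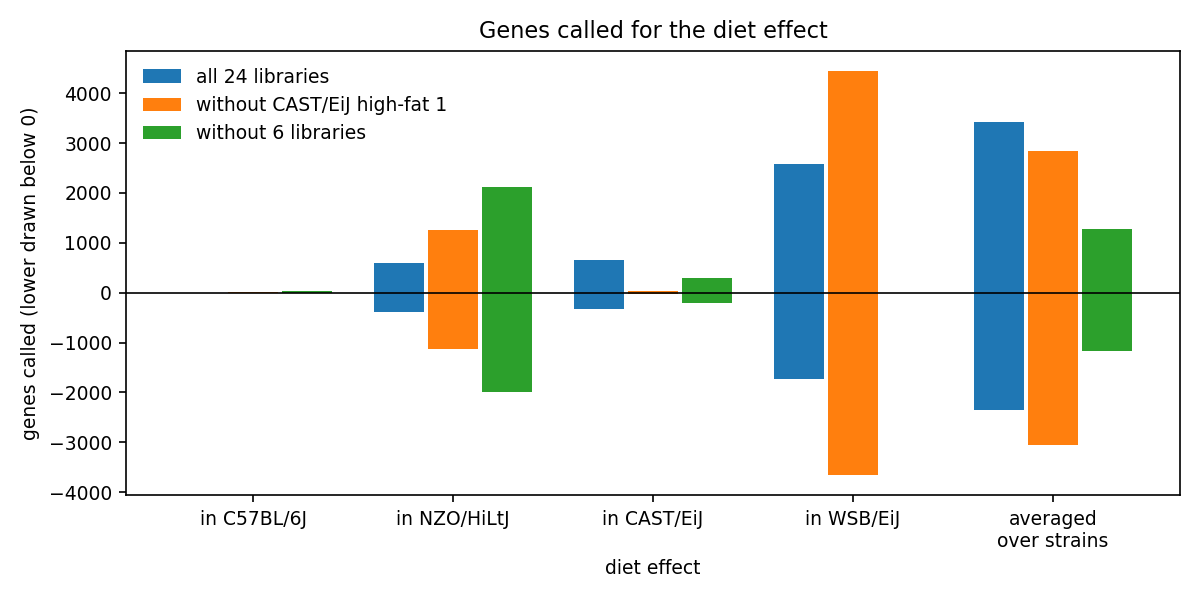
Number of genes called by edgeR for each diet effect (horizontal axis), with genes higher on the high-fat diet drawn above 0 and lower ones below 0 (vertical axis). Bars stand for all 24 libraries, for the set without replicate 1 of the CAST/EiJ high-fat group (8104 calls in WSB/EiJ) and for the set without 6 libraries, which has no value in WSB/EiJ and averages the other 3 strains.

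The diet effect averaged over strains is the mean of the 4 strain effects and does not test that the strains respond alike. Fbxo8, an F-box protein gene, fell from 36.7 ± 7.46 to 26.8 ± 2.76 CPM (-0.43 ± 0.06, adjusted p = 0.000532, n = 12), and was the only gene that met the rule for largest changes. The proliferation genes rose in 11 of 11, with Mki67 (1.81 ± 0.25, adjusted p = 0.000708), Top2a (1.85) and Ccna2 (1.41) among these. Macrophage genes rose in 8 of 15 (9 over the list alone), including Cd68 (0.66), Adgre1 (0.69), Itgax (1.35) and Ctss (1.02), and stress genes in 9 of 13, including Atf3 (1.04) and Fos (1.27). Oxidative phosphorylation genes fell in 18 of 22 (22 over the list alone), with Cox4i1 at -0.51 and Atp5c1 at -0.46. Of the adipocyte genes Slc2a4 (-0.84) and Cfd (-1.39), the adipsin gene, fell, and Irs1, an insulin receptor substrate, fell by 0.71. Scd2 rose (1.06) while Elovl6 fell (-1.38). The interaction passed for Cd68, Adgre1, Itgax, Atf3, Scd2 and Elovl6. Cd68 and Adgre1 changed by 1.89 and 2.02 in NZO/HiLtJ and by at most 0.46 and 0.38 in the other strains, Itgax by 3.42 in NZO/HiLtJ and 0.05 in CAST/EiJ, and Elovl6 by 1.41 in C57BL/6J. Clock genes moved both ways, with Npas2 (1.54) and Arntl (0.90) higher and Dbp (-0.97), Tef (-0.59) and Per3 (-0.67) lower.

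In all, 3426 genes were higher and 2362 lower averaged over strains, against 2839 and 3053 without replicate 1 of the CAST/EiJ high-fat group and 1268 and 1166 without the 6 libraries, averaged over the 3 strains other than WSB/EiJ. For the diet effect averaged over strains, the 3 covariates left 317 higher and 128 lower, and limma gave 1694 higher and 2601 lower. Leaving out replicate 1 of the C57BL/6J high-fat group gave 3651 calls. By camera 13 of 24 lists passed and none did with an estimated correlation, the lowest adjusted p being 0.322. Lists higher were proliferation, matrix, macrophage, interferon, mammary epithelium and stress genes. Lists lower were sulfide, adipocyte, fatty acid synthesis, oxidative phosphorylation, fatty acid oxidation, insulin signalling and endothelium. In that average of 3 strains, which lacks the diet effect in WSB/EiJ, the fatty acid synthesis, insulin signalling, mammary epithelium and endothelium lists did not pass (adjusted p = 0.794, 0.133, 0.994 and 0.368).

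The strain by diet interaction, which tests whether the diet effect differs between strains, passed for 618 genes, against 253 with the 3 covariates, 3588 without replicate 1 of the CAST/EiJ high-fat group and 1367 without the 6 libraries, tested over the 3 strains other than WSB/EiJ. Leaving out single libraries gave 129 to 3588 calls. The count was 129 to 350 without any 1 of the 3 C57BL/6J standard-diet, 6 NZO/HiLtJ or 3 WSB/EiJ standard-diet libraries or replicate 3 of the CAST/EiJ standard-diet group, and 1131 to 1265 without replicate 2 or 3 of the CAST/EiJ high-fat group or replicate 1 or 3 of the WSB/EiJ high-fat group. Zranb3 had the smallest adjusted p among the genes named here (5.09e-05), with 3.71 in NZO/HiLtJ and -0.01 to 0.30 in the other strains. Thbs1, the thrombospondin gene, changed by -2.31 ± 0.42 in C57BL/6J and by 2.07 ± 0.42 in WSB/EiJ (adjusted p = 0.00395), and Elovl6 by 1.41 ± 0.63 in C57BL/6J and -2.51 to -2.09 in the others (adjusted p = 0.0473).

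**Figure D4:**
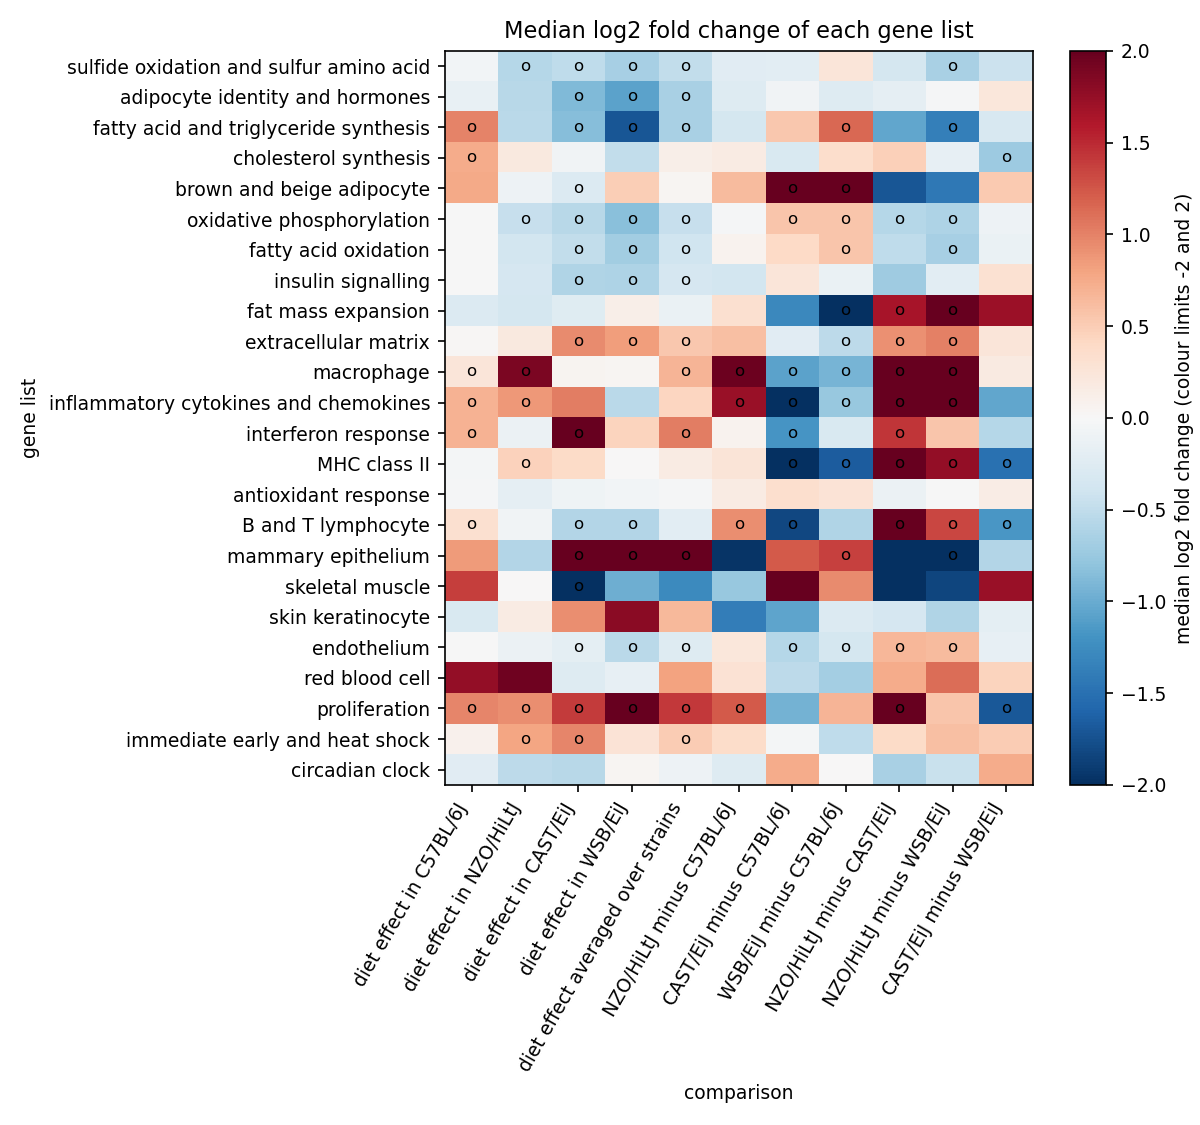
Median log2 fold change (colour, limited to -2 and 2) of 24 gene lists (vertical axis) in 11 comparisons (horizontal axis). Circles mark lists past an adjusted p of 0.05 by camera with the preset correlation, 13 of these for the diet effect averaged over strains.

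The test of any difference between the 4 strains passed for 13670 of 20035 genes, and the 6 pairs of strains had 4690 to 10246 calls. How far differences in the alignment of reads between strains enter these calls was not tested. NZO/HiLtJ against C57BL/6J had 2387 genes higher and 2303 lower, and 7128 in all without replicate 1 of the CAST/EiJ high-fat group. Itgad, an integrin of macrophages, was at 281 ± 241 against 2.79 ± 2.39 CPM (6.33 ± 0.48, adjusted p = 3.63e-08, n = 6), Cd68 was higher by 1.74 and Itgax by 3.56, while Cd163, a scavenger receptor of resident macrophages, was lower (-2.23). Macrophage genes were higher in 12 of 15 with 1 lower, and cytokine genes in 10 of 16, with both lists at adjusted p = 0.0245 with an estimated correlation. Lymphocyte genes such as Cd4 and Ms4a1 were higher in 8 of 21, 10 over the list alone, and proliferation genes in 10 of 11, 11 over the list alone, at adjusted p = 0.509 and 0.648 with an estimated correlation. The largest rises were in BC018473, Ifi202b, Mrap2, Brinp2, Ctnna2, H2-Q2 and Fam196b (6.81 to 10.97). The lowest were Pcp4, Scd4, Eps8l1, Pgr, Zfp982, Cnn1, Actg2 and Gstm6 (-7.34 to -4.70). Of these, Cnn1 and Actg2 are also smooth muscle markers. That marker list summed to 79.6 to 102 CPM in NZO/HiLtJ and 112 to 704 CPM in C57BL/6J libraries. Scd4 lay at 0.465 ± 0.19 against 71.7 ± 54.2 CPM, and how its reads were split from other desaturases is uncertain. Cth was higher (1.03), and Cbs (-2.16), Sqor (-0.82) and Suox (-0.73) were lower.

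CAST/EiJ against C57BL/6J had 3754 genes higher and 4057 lower, and 2322 calls in all with the 3 covariates. All 7 MHC class II genes were lower, with Cd74, the invariant chain, at 90.2 ± 20.1 against 801 ± 162 CPM (-3.15 ± 0.18, adjusted p = 1.38e-10, n = 6), and 17 of 21 lymphocyte genes were lower (18 over the list alone), with Ighm at -4.03. Brown and beige adipocyte genes were higher in 12 of 14, with Cidea at 50.9 ± 39.3 against 3.13 ± 2.77 CPM (4.06 ± 0.72) and Elovl3 at 5.48, while Prdm16 was lower (-1.20). Macrophage genes such as Cd68 (-1.41) were lower in 8 of 15 with 1 higher, cytokine genes in 10 of 16 with 1 higher, and endothelial genes such as Pecam1 (-1.68) in 8 of 11. The 8 lists that passed by camera had adjusted p of 0.246 to 0.867 with an estimated correlation. Mir692-3 had a count of 0 in all 6 C57BL/6J libraries and lay at 7.54 ± 3.46 CPM. Gsdma3, Tspan10, Tas1r1, Chrnb4, Adgrg7, Muc20 and Gchfr were higher by 6.07 to 9.65, and Adgrg7 and Muc20 by 3.17 and 4.74 without replicate 1 of the high-fat group. Fam213b, Iigp1, Spink1, Spaca1, Cd209f, Tmem45b, Wfdc21 and Ms4a7 were lower (-8.20 to -5.83). Of these, Spink1 (12.8 ± 30.1 CPM in C57BL/6J) went from -7.00 to -3.92 without the 6 libraries, and Tmem45b and Ms4a7 went from -5.99 and -5.83 to -8.53 and -7.11 without replicate 1 of the CAST/EiJ high-fat group.

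WSB/EiJ against C57BL/6J had 2639 genes higher and 3281 lower. Lep, the leptin gene, was at 58.9 ± 18.1 against 719 ± 354 CPM (-3.62 ± 0.81, adjusted p = 0.00274, n = 6), and Mest, an imprinted gene that follows fat mass, at 8.88 ± 2.1 against 482 ± 455 CPM (-5.73 ± 0.90, adjusted p = 0.000121). Of the 7 fat mass expansion genes 6 were lower, with Npr3 (-3.19) and Sfrp5 (-5.74) among these, and 7 over the list alone. Lipid synthesis genes were higher in 9 of 20, with Elovl6 at 3.73 and Acacb at 3.02, brown and beige genes in 10 of 14, with Ppargc1a (2.33) and Cidea (4.16), and fatty acid oxidation genes in 6 of 16, with Hadha (1.34). Macrophage genes such as Cd68 (-0.92) were lower in 10 of 15 and MHC class II genes in 7 of 7, with H2-Eb1 at 1.37 ± 0.37 against 186 ± 35.1 CPM (-7.09). The 11 lists that passed had adjusted p of 0.359 to 0.685 with an estimated correlation. Elf5, a mammary epithelial factor, was higher (4.14, adjusted p = 0.0225), and not with standard-diet groups only (-0.17, adjusted p = 0.962, for Elf5, WSB/EiJ minus C57BL/6J). Cwc22, a splicing factor gene with variable copies between strains, lay at 2664 ± 173 against 60.01 ± 4.86 CPM (5.47 ± 0.09). Mill1, Ifi202b, Sprr2f, Elovl3, Gchfr and Ptprn2 were higher by 6.05 to 7.20, and Sprr2f, also a reproductive tract marker, did not pass with standard-diet groups only (4.36, adjusted p = 0.223, for Sprr2f, WSB/EiJ minus C57BL/6J), and Klf14, Wfdc21, Cyp4f16, Methig1 and Scd4 were lower (-8.77 to -5.66).

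Among the other pairs, NZO/HiLtJ against CAST/EiJ had 5026 genes higher and 5220 lower, NZO/HiLtJ against WSB/EiJ 4344 and 4787, and CAST/EiJ against WSB/EiJ 3470 and 3636. With the 3 covariates these pairs had 1391, 4345 and 3711 calls in all. In NZO/HiLtJ, Tph2, a tryptophan hydroxylase, was at 52.4 ± 11.5 CPM against 0.0821 ± 0.06 CPM in CAST/EiJ and 0.0482 ± 0.04 CPM in WSB/EiJ (SD, n = 6). Wfdc17, BC018473, Ifi202b and Fam213b were higher in NZO/HiLtJ than in CAST/EiJ (8.86 to 10.57), and Igkv6-20, Slc5a7 and Itgad were higher in NZO/HiLtJ than in WSB/EiJ (7.99 to 8.84). Chst4, Tas1r1 and Actn2 were lower in NZO/HiLtJ than in CAST/EiJ (-8.73 to -8.60), and Mir692-3 had a count of 0 in all 6 NZO/HiLtJ libraries. Lower in NZO/HiLtJ than in WSB/EiJ were Mill1 and Rxfp1 (-9.48 and -9.06), and with standard-diet groups only Rxfp1 did not pass (-6.78, adjusted p = 0.0922, for Rxfp1, NZO/HiLtJ minus WSB/EiJ). Mir692-3, Gsdma3 and Tspan10 were higher in CAST/EiJ than in WSB/EiJ (10.21 to 10.97), and St6galnac5, Iigp1 and Ifi202b were lower (-7.27 to -6.79). Macrophage genes were higher in NZO/HiLtJ in 12 of 15 against CAST/EiJ, with 1 lower, and in 14 of 15 against WSB/EiJ, at adjusted p = 0.0929 and 0.0232 with an estimated correlation. Cytokine genes were higher in 13 of 16, with 1 lower, and in 15 of 16, at adjusted p = 0.048 and 0.0232. By camera 10, 12 and 4 of the 24 lists passed in the 3 pairs, and 9 of 20 cholesterol synthesis genes were lower in CAST/EiJ than in WSB/EiJ (list adjusted p = 0.909 with an estimated correlation).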

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

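The tests of the CAST/EiJ library, of lower Tst in WSB/EiJ and of mesothelial transcripts were chosen only after the result was seen, while the tests of other splits of the samples were planned.

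The diet effect differed between strains for 618 genes by the test of the strain by diet interaction, which is what brought these and the genes named here to attention. There were 21 splits of the libraries, the real one and 20 drawn. Only the real 1 gave as many interaction calls, and the highest other split gave 84. A share of 1 in 21 is under 0.05, but no smaller share was possible. Exchanging diets within a strain removes every diet effect, shared ones included. These splits therefore cannot tell an interaction from a diet effect that the strains share. Genes that rose most in NZO/HiLtJ were Zranb3 (interaction adjusted p = 5.09e-05), Cd68 (0.00181), Adgre1 (0.00764), Msr1 (0.0127), Itgax (0.0282), Atf3 (0.0282) and Gpr50 (0.0485). Genes with negative values in NZO/HiLtJ and CAST/EiJ and positive ones in WSB/EiJ were Slc38a3 (0.01), Cyp2a4 (0.0126), Ces1c (0.0249), Pzp (0.0281), A1bg (0.0297), Slc27a2 (0.0297), Cyp3a41a (0.0353), Cyp3a41b (0.0358) and Cyp2a5 (0.0482). Liver marker sums moved the same way. They went from 753, 1290 and 130 to 31.1, 17.9 and 5.84 CPM with the high-fat diet in NZO/HiLtJ, from 46, 670 and 174 to 23.2, 7.75 and 24.3 CPM in CAST/EiJ, and from 26.4, 36.6 and 16.2 to 82.9, 73.3 and 265 CPM in WSB/EiJ. Genes of lipid and cholesterol synthesis with a higher value in C57BL/6J than in WSB/EiJ were Fdft1 (0.00274), Cyp51 (0.0312), Scd2 (0.0428), Elovl5 (0.0446) and Elovl6 (0.0473).

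Further genes with an interaction were Thbs1 (adjusted p = 0.00395), Podnl1 (0.0126), Prlr (0.0146), Pik3c2g (0.0311), Aspg (0.0415), Cth (0.0453), Krt8 (0.0454), Mill1 (0.0473), Col1a1 (0.0474), Gjb6 (0.0479) and Ccn5 (0.0489). Pik3c2g changed by 3.64 ± 1.17 in C57BL/6J and -3.16 ± 0.74 in WSB/EiJ, and Aspg by 3.72 ± 1.00 and -2.99 ± 0.94. Cth changed by 0.65 ± 0.35 in C57BL/6J and by -1.44 ± 0.36 in CAST/EiJ and -1.62 ± 0.36 in WSB/EiJ. Krt8 and Col1a1 had higher values in CAST/EiJ (4.38 and 1.93) and WSB/EiJ (4.50 and 2.01) than in C57BL/6J (0.30 and 0.17).

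In the diet effect in CAST/EiJ, the calls and their loss without replicate 1 of the high-fat group formed the pattern weighed first. Of 10 reproductive tract genes, 9 were at 5 CPM or more in that library and at 10 times or more the highest other library of the strain, with Ltf at 1350 CPM, consistent with tissue of the reproductive tract. The value was written into a test after the library had been seen, and 4 of the 10 genes are also named in the comparisons. A sample of another strain is argued against, since 70 of 95 genes found only in the other 5 CAST/EiJ libraries at 1 CPM or more were detected in it, and 2 of the 3 at a count of 0 in all other strains. A diet response of the strain stays open, since 79.3% of the called genes (773 of 975) had replicates 2 and 3 beyond the 3 standard-diet libraries. That share was taken over genes called with those same replicates, and a diet response cannot be told apart from other tissue for these genes.

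Lower Tst with the diet effect in WSB/EiJ was weighed second. Fewer adipocyte transcripts are argued against as the whole cause, since Tst minus the mean of 16 adipocyte genes went from -3.79 on the standard to -4.71 on the high-fat diet (log2), a change of -0.925 with a pooled SD of 0.317. Liver RNA in the standard-diet libraries is argued against as well, since Alb was at most 25.5 CPM there against at least 76.8 CPM in NZO/HiLtJ on the same diet. With covariates for mammary epithelial, lymphocyte and skeletal muscle RNA, Tst went from -2.09 ± 0.50 to -0.89 ± 0.57. The adjusted p was 0.385 (range over alternatives 0.000397 to 0.385). The call ended with both a smaller change and a larger standard error. Epcam, of the epithelial list, lay at 0.287, 0.22 and 5.67 CPM on the standard and 33.1, 58.5 and 11.9 CPM on the high-fat diet. The fit therefore cannot separate epithelial RNA from the diet. If Tst comes from adipocytes, dilution by such RNA would lower it and the adipocyte genes alike. The change of -0.925 then argues against dilution as the whole cause. Such RNA as part of the cause stays open, and so does a response of the strain to the diet. Smooth muscle, brain and urothelial RNA had no covariate and was not tested.

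Mesothelial transcripts in libraries labelled inguinal were weighed last. Wt1, a gene of mesothelium and intra-abdominal fat, was at 15.6 to 136 CPM, and 24 of 24 libraries reached 5 CPM, while of the 5 genes of subcutaneous fat, Tbx15, Shox2, En1 and Hoxc9 stayed below 5 CPM in 24 of 24 and Sfrp2, at 6.53 to 45.5 CPM, reached it in 24 of 24. The test used Tbx15, Shox2 and En1 alone, so the subcutaneous genes as a whole leave the depot open. High Wt1 may come from fat of an intra-abdominal depot, or from intra-abdominal tissue taken along with it. Mesothelium that came only with reproductive tract tissue is argued against, since 18 of the 18 libraries with Epcam below 5 CPM reached it too. No biological explanation was tested, since the labels give 1 depot.

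The 6 libraries of a strain have 10 splits for each diet effect, the real one included, which are too few for a share under 0.05. The real split gave 2 calls in C57BL/6J, 979 in NZO/HiLtJ, 975 in CAST/EiJ and 4305 in WSB/EiJ, and the highest other splits gave 0, 0, 16 and 5. The next comparisons had 21 splits each, the real one included, and only the real 1 gave as many calls. These were the average diet effect (5788, highest other 12) and the test of any strain difference (13670, highest other 8). Against C57BL/6J they were NZO/HiLtJ (4690, highest other 1312), CAST/EiJ (7811, highest other 1688) and WSB/EiJ (5920, highest other 2913). The last were NZO/HiLtJ against CAST/EiJ (10246, highest other 7089) and against WSB/EiJ (9131, highest other 3985). A share of 1 in 21 is under 0.05, but is the smallest that 21 splits can give and was not adjusted over comparisons. Chance is argued against for these but not excluded. For CAST/EiJ against WSB/EiJ, 2 of 21 splits gave as many, 7106 in the real split and 7324 with replicate 1 of the CAST/EiJ high-fat group and replicate 3 of the WSB/EiJ high-fat group exchanged. By this count chance is not argued against there, though that split moves only 2 libraries and leaves the others of each strain together. The median of the other splits was 1 call.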

How the results depend on the processing

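Added to the alternatives, and chosen after seeing the data, were limma with 0.01 added, leaving out 2 libraries together and leaving out the 6 libraries with Epcam at 5 CPM or more. The WSB/EiJ diet effect could not be fitted without the 6 libraries and gave no value, so the average and interaction of that set cover 3 strains, and its pairs with WSB/EiJ set both diets of the other strain against the standard diet of WSB/EiJ alone. Changes in these differ from the full set by construction. Unless stated, the cause was not tested. Other scaling factors (relative log expression, upper quartile) kept every count within 1.5 times, and shifted the median of all genes by less than 0.1 (log2). No paired analysis was possible because the labels give no replicate number that groups share.

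Without a count filter, the diet effect in CAST/EiJ had 239 calls and Tst there was -1.89 (adjusted p = 0.057, range over alternatives 0.00328 to 0.628), and the interaction had 393. With 1 CPM in 6 libraries the diet effect in C57BL/6J had 1 call. DESeq2 called 36 genes (27 higher, 9 lower) in C57BL/6J, 1610 in NZO/HiLtJ, 2872 in CAST/EiJ and 2641 for the interaction, where Tst passed (adjusted p = 0.0306, range 0.0246 to 0.326). With limma and 1 added, C57BL/6J had 15 (10 higher, 5 lower), CAST/EiJ 440 (101 higher, 339 lower), WSB/EiJ 2738 (1177 higher, 1561 lower) and the interaction 935, with Tst at 0.0246, and the average effect had 1694 higher and 2601 lower. With 0.01 added, C57BL/6J had 4, CAST/EiJ 316 (110 higher, 206 lower) and the average 2077 higher and 2558 lower.

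With the 3 covariates, the diet effects had 4 calls in C57BL/6J, 1854 in NZO/HiLtJ, 7 in CAST/EiJ (7 higher, 0 lower), 80 in WSB/EiJ (36 higher, 44 lower) and 445 on average (317 higher, 128 lower), and the interaction 253. Tst had -1.33 in CAST/EiJ, -0.89 in WSB/EiJ (range of adjusted p 0.000397 to 0.385) and -0.69 on average (7.06e-05 to 0.213). In CAST/EiJ, Padi1 (-0.84), Muc1 (-0.72) and Mylpf (0.004) reversed, in WSB/EiJ Tbc1d4 (0.005) and Prdx1 (0.016), and -0.093 was the value of 1 more gene (Npas2, diet effect averaged over strains). CAST/EiJ against C57BL/6J had 2322 calls (Tst 1.88), NZO/HiLtJ against CAST/EiJ 1391 (Tst -2.49), NZO/HiLtJ against WSB/EiJ 4345 and CAST/EiJ against WSB/EiJ 3711.

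With standard-diet groups only, NZO/HiLtJ minus C57BL/6J had 1675 calls and Tst reversed to 0.36, Elf5 in WSB/EiJ minus C57BL/6J reversed to -0.17, and NZO/HiLtJ and CAST/EiJ against WSB/EiJ had 5636 and 4705. High-fat groups only gave, against C57BL/6J, 2976 calls in NZO/HiLtJ, 5198 in CAST/EiJ with Tst at 0.66 (range of adjusted p 3.31e-06 to 0.34) and 3589 in WSB/EiJ with Tst at 1.03 (3.56e-09 to 0.156), with fewer libraries per strain. Fits of 1 strain, with 4 residual degrees of freedom, called 0 genes in C57BL/6J and 0 in CAST/EiJ, where edgeR with all libraries called 2 and 975 and had 734 and 5778 below an unadjusted p of 0.05. DESeq2 and limma on all libraries called 36 and 15 in C57BL/6J and 2872 and 440 in CAST/EiJ. The same fits called 5967 in NZO/HiLtJ (2948 higher, 3019 lower), with Tst passing (-0.87, range of adjusted p 0.00565 to 0.732), and 1488 in WSB/EiJ (575 higher, 913 lower), and Tst in CAST/EiJ was -1.88 without passing.

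Without replicate 1 of the CAST/EiJ high-fat and replicate 2 of the WSB/EiJ high-fat group, calls were 36 in C57BL/6J, 3208 in NZO/HiLtJ, 206 in CAST/EiJ (Tst -1.46), 3448 for the interaction and 8063 for NZO/HiLtJ against C57BL/6J. Without the 6 libraries they were 30, 4112, 505 (Tst -1.46), 1367 (over 3 strains) and 8409, with 2434 on the average of 3 strains (Tst -0.67). Against the standard diet of WSB/EiJ alone, Elf5 in WSB/EiJ minus C57BL/6J reversed to -1.13 and Tst in CAST/EiJ against WSB/EiJ passed at -1.41 (range of adjusted p 0.0142 to 0.629), while like diets gave -0.57 (standard) and -0.37 (high-fat) for Tst, CAST/EiJ minus WSB/EiJ, and neither passed. Lists called without these were 8 for the CAST/EiJ diet, 13 for CAST/EiJ against C57BL/6J and 10 for CAST/EiJ against WSB/EiJ on the standard diet. A minimum absolute change of 1, which removes calls by construction, left 2403 in WSB/EiJ (2054 higher, 349 lower), 1576 on average (1199 higher, 377 lower), and for strain pairs 2145 (NZO/HiLtJ minus C57BL/6J), 3619 (CAST/EiJ minus C57BL/6J), 2438 (WSB/EiJ minus C57BL/6J), 5098 (NZO/HiLtJ minus CAST/EiJ), 4312 (NZO/HiLtJ minus WSB/EiJ) and 3437 (CAST/EiJ minus WSB/EiJ).

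Lists called with an estimated correlation were 0 for the diet in C57BL/6J, 1 in NZO/HiLtJ, 0 in CAST/EiJ, 0 in WSB/EiJ, 0 on average, 2, 0 and 0 for NZO/HiLtJ, CAST/EiJ and WSB/EiJ against C57BL/6J, and 1, 2 and 0 for the other pairs. By fry they were 0, 4, 3 and 4 for the diet in those strains, 8 on average and 7 for WSB/EiJ against C57BL/6J. Leaving out replicate 1 of the CAST/EiJ high-fat group gave 8, 10, 7, 11 and 13 lists for the diet effects, 7, 12 and 12 against C57BL/6J, and 14, 14 and 6 for the other pairs.

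Leaving out 1 library at a time gave, for the diet effects, 0 to 21 calls in C57BL/6J, 272 to 2375 in NZO/HiLtJ, 4 to 4778 in CAST/EiJ, 639 to 8104 in WSB/EiJ and 3651 to 7803 on average. The interaction had 129 to 3588 and the test of any strain difference 12957 to 16302. Strain pairs had 3674 to 7128 (NZO/HiLtJ minus C57BL/6J), 6894 to 9940 (CAST/EiJ minus C57BL/6J), 4721 to 8717 (WSB/EiJ minus C57BL/6J), 9396 to 11815 (NZO/HiLtJ minus CAST/EiJ), 8066 to 11555 (NZO/HiLtJ minus WSB/EiJ) and 6367 to 10121 (CAST/EiJ minus WSB/EiJ). Tst moved from -0.23 to 0.59 in C57BL/6J, -1.05 to -0.75 in NZO/HiLtJ, -2.75 to -1.33 in CAST/EiJ, -2.21 to -1.89 in WSB/EiJ and -1.37 to -1.02 on average. Its adjusted p was 0.0307 to 0.254 for the interaction and 8.66e-07 to 5.38e-05 over strains. Between strains, in the order above, Tst moved from -0.31 to 0.04, 1.29 to 1.94, 2.06 to 2.41, -2.11 to -1.47, -2.46 to -2.27 and -0.90 to -0.26.

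Reversals with 1 library left out were Tst in NZO/HiLtJ minus C57BL/6J (0.006 without replicate 2 of the C57BL/6J standard-diet group and 0.043 without replicate 3 of its high-fat group), Tst for the diet in C57BL/6J (-0.047 without replicate 3 of the standard-diet and -0.226 without replicate 3 of the high-fat group), and 2 genes of the diet effect in WSB/EiJ without replicate 3 of its high-fat group. Their values over these fits were -0.002 to 5.34 (Trp63, diet effect in WSB/EiJ) and -0.37 to 2.60 (Gpnmb, diet effect in WSB/EiJ). Over all summaries, 547 values of fits without 1 library kept their direction and side of the threshold, 19 passed newly or rose by over 1.5 times, 65 did not pass any more or fell by over 1.5 times, and 4 reversed. For other alternatives these counts were 248, 24, 64 and 1. Named genes were weaker in the same sense in 935 fits without 1 library and kept their direction and side in 6743, and were weaker in 159 cases with the covariates, 48 without the 6 libraries (pairs with WSB/EiJ and averages included), 83 by limma with 1 added and 15 by DESeq2. At 40.06% variation between mice and 3 mice per group, the simulation recovered 32 of 100 genes changed 2-fold in C57BL/6J, so changes of that size were often not detectable.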

Other observations

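The summed levels of marker lists of other tissues and fat depots, which enter no comparison, were highest for 6 of 10 lists in a library of the CAST/EiJ or WSB/EiJ high-fat group. Kidney genes reached 4020 CPM in replicate 1 of the CAST/EiJ high-fat group, through Kap alone, with 114 CPM as the next highest. Genes of milk and basal epithelium reached 213 CPM in replicate 3 of the WSB/EiJ high-fat group, with 3.88 CPM as the next highest. That sum came through Krt5, which is also in the urothelium list, highest in the same library. Reproductive tract genes reached 1040 CPM in replicate 2 and 788 CPM in replicate 1 of the WSB/EiJ high-fat group. Liver genes reached 1290 and 753 CPM in replicates 2 and 1 of the NZO/HiLtJ standard-diet group, against a median of 65.7 CPM over libraries. Mesothelial genes summed to 46.8 to 402 CPM, genes of subcutaneous depots to at most 51.7 CPM, and genes of intra-abdominal depots to at most 181 CPM, with a median of 80.9 CPM. Msln and Upk3b, which encode mesothelial surface proteins, lay at 5.4 to 97.9 and 8.38 to 137 CPM.

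The spread between libraries of a group was uneven. Plin1, the perilipin of fat droplets, lay between 1.11 and 561 CPM over the 24 libraries. The biological coefficient of variation was 40.06% with all libraries and 20.77% without the 6 with Epcam at 5 CPM or more, and the diet effect in NZO/HiLtJ, whose libraries are all kept, rose from 979 to 4112 calls. The larger count may come from the smaller spread estimated without these 6 libraries, which was not tested apart from this refit. The libraries kept still held markers of other tissue. In replicate 2 of the NZO/HiLtJ standard-diet group, liver genes summed to 1290 CPM and kidney genes to 114 CPM. In a fit of the 6 NZO/HiLtJ libraries alone, 5967 genes were called.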
